A study of Mus musculus with 14 samples.

How the data were processed

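Glomeruli were enriched from the kidneys of 4 mice with an inducible, podocyte-directed Ctcf deletion (KO) and 4 WT mice after 1 week of doxycycline, and single cells were profiled on a droplet platform that reads the 3' end of transcripts, per the labels' protocols. The mice were 2 months old. The 8 mice gave 14 libraries, since 6 mice had a pair of libraries, A and B, and the libraries of a mouse were added before any test. The mouse was the replicate throughout. The KO mice were 2 males and 2 females, and the WT mice 1 male and 3 females. The levels of Xist and Ddx3y in podocytes and endothelial cells of each mouse went with the sex in its label.

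The deposited values were counts of unique molecular identifiers (UMIs) per gene and droplet barcode, with no normalisation. They were made by the authors with Cell Ranger 2.1.1 on the mm10 build, per the submitters' processing notes. Barcodes had not been filtered: the matrices also held barcodes with very few UMIs. Library totals ran from 15193597 to 69025051 UMIs. Reads, intronic counting settings and the annotation used for counting were not given in the sources used here.

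Barcodes with at least 500 genes and 1000 UMIs and at most 20% mitochondrial UMIs were kept. Scrublet, as run in scanpy 1.11.5 on each library, marked 716 of 49256 barcodes (1.45%) as doublets, and these were removed, leaving 48540 cells. The marked share ran from 0.126% to 2.52% per library, so doublets remain in the data. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 components were used, and a graph of 15 neighbours was clustered by the Leiden method at resolution 1.0, which gave 32 clusters. No integration across libraries was applied. Clusters were named from marker lists. A cluster was kept apart as mixed where at least 0.5 of the markers of each of several unrelated cell types, in or outside the filter, were detected in at least 0.25 of its cells. This rule was set after the clusters had been seen. These mixed clusters held 3.70% ± 1.25 of the cells of KO mice and 4.61% ± 2.35 of those of WT mice (SD, n = 4 each; exact permutation p = 0.457). Clusters left without a name held 1.38% ± 0.61 and 1.45% ± 0.73.

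Counts were summed per mouse and class and tested with the quasi-likelihood test of edgeR 4.0.16 (default low-count filter, TMM scaling, robust fit), with Benjamini-Hochberg adjustment over the genes tested in each class and a threshold of 0.05. DESeq2 1.42.0 was run beside it. Standard errors of log2 fold changes were taken from the F statistic. CPM denotes counts of a gene scaled to the UMI total of the class in a mouse. The difference of the KO effect between podocytes and endothelial cells was tested as an interaction with the mouse as a block. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry. There were 20 lists and 6 lists of cell type markers. Class shares and podocyte UMIs per cell were tested with 2-sided exact permutation tests over the 70 assignments of 4 and 4 mice.

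The groups, tests, marker lists, gene lists, ligand and receptor pairs, rule for named genes and most alternatives were chosen before the data were examined. The rule named, among genes past the threshold without overlap between the genotypes and with a mean of at least 20 CPM, the 8 largest rises and the 8 largest falls, leaving out predicted genes and pseudogenes. It added Ctcf in every class, up to 4 members of each list with the smallest p, and members of pairs in which either passed. The result of 1 gene in mesangial cells is not reported here. Gnai1, Itgae and Mnd1 in podocytes, Sntb2 in the other classes and the neighbours of risen genes fell outside the rule and were chosen after their values were seen. Gene coordinates came from a GENCODE annotation of the same assembly, in which 27645 of 27998 gene identifiers (98.7%) were found.

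The test was checked on simulated counts with 200 genes changed. In podocytes it recovered 74.5% of 2-fold and 95.9% of 4-fold changes among 10394 genes, with 18 calls among the genes left alone. In endothelial cells it recovered 69.8% and 91.8% among 11532 genes, with 9 such calls, and in mesangial cells 72.8% and 97.8% among 7335 genes, with 13. False calls were thus 9.78%, 5.45% and 7.69% of the calls in these 3 classes, all above the nominal 5%. The dispersions of single genes used here replaced trended ones after a first run of this check. Real counts of genes with an unadjusted p over 0.05, thinned in 1 genotype to keep the real spread between mice, gave 60% and 89% among 10538 genes in podocytes, 65% and 89% among 11692 genes in endothelial cells, and 49% and 77% among 7495 genes in mesangial cells. Among the genes not thinned, which kept their real differences, 155, 1 and 0 were called in these classes.

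The alternatives were other scaling, no low-count filter, DESeq2, mouse number as a block, sex as a covariate, library A only, each mouse left out, other cell filters, doublets kept, other clusterings, subtraction of free RNA (estimated from barcodes with up to 100 UMIs), and equal cells and UMIs per mouse.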

Results

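Single-cell transcriptomes of kidney glomeruli were compared between 4 KO mice, in which doxycycline had induced deletion of Ctcf in podocytes, and 4 WT littermate controls given the same treatment. Podocytes, endothelial cells and mesangial cells form the glomerular filter, and the series title names their interactions after podocyte injury as the question. The 48540 cells included 12041 podocytes, 19510 endothelial cells and 2060 mesangial cells. Podocyte sums held between 1384375 UMIs from 225 cells (WT mouse 4) and 19408412 UMIs from 5012 cells (WT mouse 2). Endothelial sums held 2807824 to 14242949 UMIs and mesangial sums 321383 to 2617344. KO mouse 4 stood apart from the other mice: before the mitochondrial filter its libraries had a median mitochondrial share of 20.3% and 19.6%, and proximal tubule cells made up 27.0% of its kept cells.

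Ctcf, which encodes a DNA-binding protein at the anchors of chromatin loops, fell in KO podocytes. Its level was 14.9 ± 5.06 CPM in KO and 57.2 ± 7.47 CPM in WT podocytes (SD, n = 4 each), a log2 fold change of -1.96 (SE 0.21, edgeR adjusted p = 0.00104). The KO mice had 16.1, 9.60, 12.6 and 21.4 CPM, and the WT mice 48.2, 59.1, 55.3 and 66.2 CPM. The gene (ENSMUSG00000005698) lies on chromosome 8 at 105636568 to 105682922 (mm10). The 3' tags need not lie in the deleted exons, so the remaining UMIs do not measure the share of cells without deletion. Ctcf did not pass the test in any other class: the log2 fold change was 0.17 (SE 0.16) in endothelial and 0.36 (SE 0.21) in mesangial cells, and from -0.12 to 0.22 in the 5 other classes tested.

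**Figure D1:**
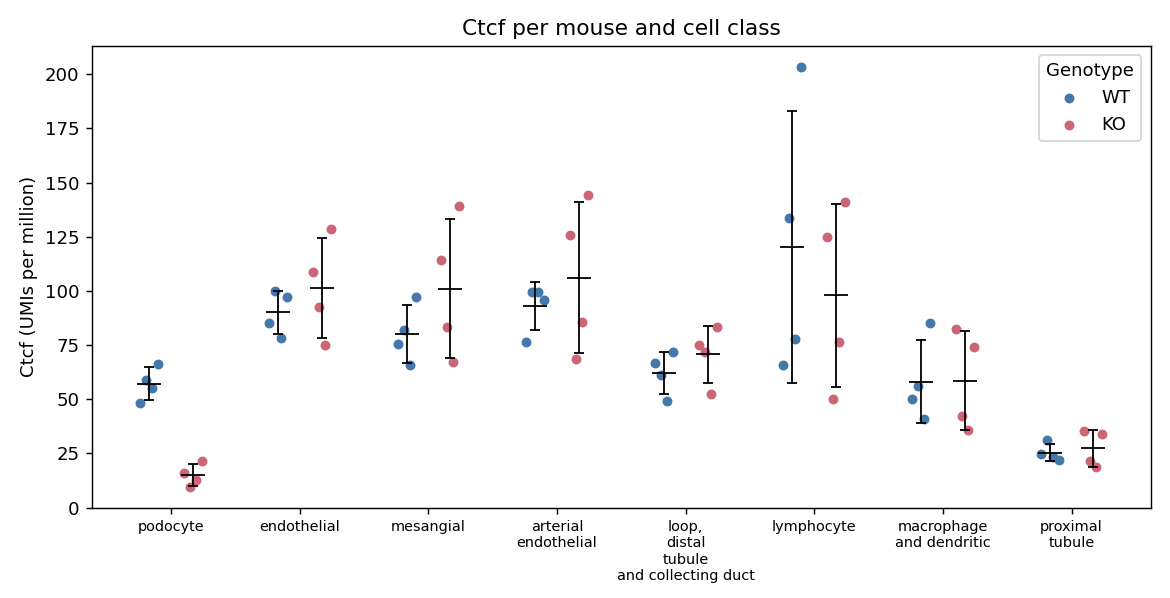
Ctcf in CPM (vertical axis) for each mouse in 8 cell classes; points are mice, bars the mean ± SD of 4 mice per genotype. In podocytes the KO mice lie between 9.60 and 21.4 and the WT mice between 48.2 and 66.2.

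In podocytes, 97 genes changed, 71 higher and 26 lower in KO mice, of 10548 tested. Sntb2, which encodes a syntrophin adaptor protein, rose most among the genes the rule named, from 7.52 ± 1.68 to 67.5 ± 10.4 CPM (log2 fold change 3.18, SE 0.18, edgeR adjusted p = 3.67e-06). Lxn, an inhibitor of carboxypeptidases, rose from 25.2 ± 3.98 to 70.3 ± 5.13 CPM, and Serpinb9, an inhibitor of granzyme B, from 38.9 ± 6.36 to 94.5 ± 7.77 CPM. The tetraspanin gene Tspan32 rose from 10.9 ± 1.34 to 31.9 ± 5.53 CPM. Mustn1, Prps2, Mettl25 and Npdc1 rose by log2 fold changes of 1.88, 1.17, 1.15 and 0.99. Ehd2, which encodes a caveola-associated ATPase, fell from 179 ± 14.7 to 88.5 ± 11.8 CPM, and the calcium-binding protein gene S100a1 had a log2 fold change of -1.07 (SE 0.16, edgeR adjusted p = 0.0103). The secreted protease gene Adamts1 and the calcitonin gene Calca had log2 fold changes of -1.40 and -1.04, and Abhd14b -1.33. Ndufaf3, an assembly factor of respiratory complex I, and Ppa2, the mitochondrial pyrophosphatase, had log2 fold changes of -0.92 and -0.85. Below the expression minimum, and chosen after their values were seen, Gnai1, an inhibitory G protein subunit, had 145, 245, 217 and 100 UMIs in the KO mice and 8, 32, 8 and 2 in the WT mice, and the integrin gene Itgae had 69, 67, 60 and 40 against 0, 2, 1 and 0. Sntb2 (ENSMUSG00000041308) lies at 106935750 to 107019714 on chromosome 8 (mm10). In 628 genes (5.95%) the genotypes did not overlap, where chance gives 2.86%. DESeq2 called 178 genes. The count was 40 without KO mouse 1, 58 without KO mouse 3, 29 without WT mouse 1, 60 without WT mouse 2, 39 without WT mouse 3 and 57 without WT mouse 4, and 17 with equal cells and UMIs per mouse. With a single mouse left out, Abhd14b lost its call for every mouse but KO mouse 4 (log2 fold changes over the 8 mice -1.64 to -1.16), Mustn1 for every mouse but both mice numbered 4 (1.67 to 2.11), Adamts1 for every mouse but KO mouse 3 and WT mouse 4 (-1.60 to -1.28), and Ppa2 for every mouse but KO mice 2 and 4 (-0.93 to -0.71). Calca lost its call without KO mouse 1 or WT mouse 1, 2 or 4 (-1.16 to -0.94), and Mettl25 (1.01 to 1.23) and Npdc1 (0.90 to 1.10) without WT mouse 1 or 3. Cluster 5 held 935 of the 1116 podocytes of KO mouse 4, and cluster 0 held 3614 of the 5012 of WT mouse 2.

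**Figure D2:**
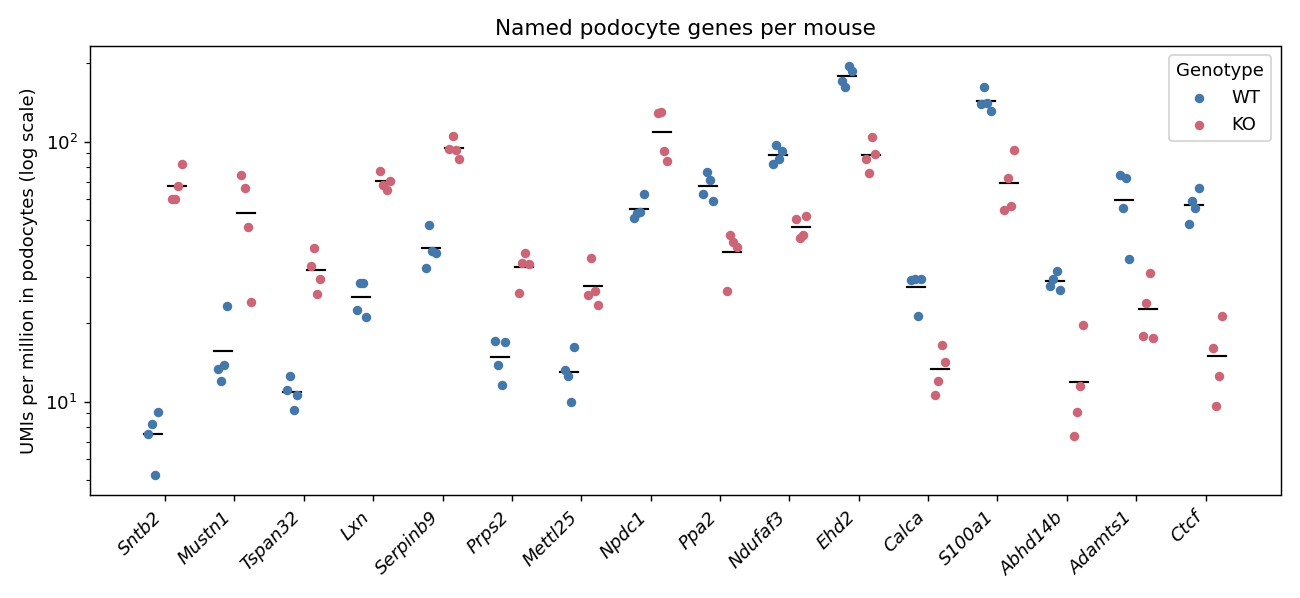
CPM in podocytes (vertical axis, log scale) for the 8 largest rises and the 8 largest falls among the genes that met the rule for named genes. Points are mice, lines the mean of 4 mice per genotype. The KO and WT mice do not overlap for any gene shown because the rule required it.

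Of the gene lists tested in podocytes, the CTCF and cohesin list held 1 gene that rose and 1 that fell among 16 measured, over all genes and adjusted over the list alone. These were Ctcf and Stag1, a cohesin subunit, with a log2 fold change of 0.85 (edgeR adjusted p = 0.0326). The median log2 fold change of this list was 0.02 and its mean -0.10, with a camera test in the direction of the mean (adjusted p = 0.598). Stag1 did not pass without any single mouse other than KO mouse 2 (log2 fold changes over the 8 mice 0.75 to 0.96). No member of any other list passed over all genes. Adjusted over the list alone, 1 of 16 glomerular basement membrane genes was higher (Sparc, log2 fold change 0.63) and 1 lower (Col18a1, -0.58), 2 of 28 interferon response genes were lower (Ifit2, -1.39, and Irf9, -1.26), and 1 of 16 podocyte markers was lower (Rhpn1, -0.62). Over all genes, Sparc passed without KO mouse 2 (0.70), Col18a1 without KO mouse 4 (-0.69) and Ifit2 without WT mouse 2 (-1.59). With the preset correlation, slit diaphragm and podocyte actin genes were lower (median log2 fold change -0.19, 29 genes, camera adjusted p = 0.00385), as were podocyte markers (-0.22, 16 genes, p = 0.00327) and interferon response genes (-0.18, 28 genes, p = 0.0222). Nuclear genes of oxidative phosphorylation were higher (0.12, 77 genes, camera adjusted p = 0.00085), as was the mitochondrial genome (0.36, 13 genes, camera adjusted p = 0.0222). None of these 5 passed with an estimated correlation, where all 25 lists tested had the same camera adjusted p = 0.922. That shared value does not rank the lists. The smallest unadjusted camera p with an estimated correlation was 0.0748, for podocyte markers. With fry, podocyte markers and nuclear genes of oxidative phosphorylation each had an adjusted p = 0.449. The mitochondrial transcript mt-Nd1 was at 8389 CPM in KO mouse 4 and at 3950 to 4253 CPM in the other KO mice, and the proximal tubule transcript Kap at 1879 CPM and at 6.64 to 271 CPM. Proximal tubule markers had a positive log2 fold change in 11 of 13 (camera adjusted p = 0.141). For the p53 target list, 13 of 25 members had a positive log2 fold change, and for imprinted genes 9 of 15, with no member past the threshold in either. Without WT mouse 2 the number of lists with a call was 3, and without WT mouse 4 it was 8.

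In endothelial cells, no gene changed among 11708 tested by edgeR, and none by DESeq2. At an unadjusted p under 0.05 there were 172 genes, a smaller share of the tested genes than chance gives. The genotypes did not overlap in 1.03% of genes, where chance gives 2.86%. The absence of calls does not show that no gene changed in endothelial cells. Adjusted over the list alone, 2 of 30 genes of the integrated stress and unfolded protein response list were lower in KO mice: Sdf2l1, an endoplasmic reticulum chaperone component, at 47.5 ± 8.86 against 71.3 ± 6.17 CPM (SD, n = 4 each), and the disulfide isomerase gene Pdia6 at 175 ± 13.6 against 239 ± 21.7 CPM. With the preset correlation this list was lower (median log2 fold change -0.11, camera adjusted p = 0.00346), podocyte markers were lower (-0.48, 15 genes, p = 2.3e-06), the mitochondrial genome was higher (0.50, 13 genes, p = 9.51e-05) and proximal tubule markers were higher (0.58, 13 genes, p = 0.00563). All 4 had an adjusted p = 0.89 with an estimated correlation. Among podocyte markers Rhpn1 was lower, adjusted over the list alone, at 2.49 ± 0.331 against 5.59 ± 2.81 CPM. The camera call of podocyte markers stayed with free RNA subtracted. It was lost without WT mouse 2, which had the highest podocyte share (43.6% of kept cells). These values need not be endothelial expression, since podocyte RNA from remaining doublets or free RNA was not excluded as their source. In KO mouse 4, mt-Cytb was at 12729 CPM and Kap at 2742 CPM, against 4987 to 5899 and 7.48 to 364 CPM in the other KO mice. The genotypes were unevenly spread over endothelial clusters: cluster 9, with a median mitochondrial share of 12.4%, held 2108 KO cells, 1928 of them from KO mouse 4, and 120 WT cells, and cluster 4 held 2327 and 1035. The number of lists with a call was 0 without WT mouse 2, 1 without KO mouse 4, 7 without KO mouse 2, 7 without WT mouse 4 and 8 without KO mouse 1.

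In mesangial cells, no gene changed among 7529 tested by edgeR, and none by DESeq2. At an unadjusted p under 0.05 there were 188 genes, again below the 5% of tested genes that chance gives. The genotypes did not overlap in 1.77% of genes, where chance gives 2.86%. Here too the absence of calls does not show that no gene changed. Adjusted over the list alone, 3 of 25 genes of the integrated stress and unfolded protein response list were lower in KO mice: Hsp90b1, an endoplasmic reticulum chaperone, at 396 ± 46.7 against 542 ± 27.5 CPM, Pdia6 at 118 ± 22.8 against 174 ± 26.9 CPM, and the serine synthesis gene Psat1 at 8.52 ± 2.70 against 17.6 ± 4.05 CPM (SD, n = 4 each). With the preset correlation this list was lower (median log2 fold change -0.18, camera adjusted p = 1.09e-06), as were interferon response genes (-0.25, 33 genes, p = 4.48e-07) and actin cytoskeleton genes (-0.05, 37 genes, p = 0.00873). Nuclear genes of oxidative phosphorylation (0.07, 74 genes, camera adjusted p = 0.0132) and proximal tubule markers (0.70, 8 genes, camera adjusted p = 0.00873) were higher. All 5 had an adjusted p = 0.764 with an estimated correlation. Proximal tubule markers lost their camera call without KO mouse 4, without WT mouse 1 and with free RNA subtracted. The median mitochondrial share of mesangial cells was 11.2% in KO mouse 4 and 5.18% to 5.65% in the other KO mice. The number of lists with a call was 3 without KO mouse 4, 3 without WT mouse 1 and 8 without KO mouse 2.

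The KO effect differed between podocytes and endothelial cells for 111 genes of 9935 tested in both, 75 with a larger log2 fold change in podocytes and 36 with a smaller one (edgeR interaction test). Of the 97 genes called in podocytes, 79 were tested here and 64 passed. These genes were picked by their effect in the same podocyte sums, so this share is not independent support. For Sntb2 the difference was 3.00 on the log2 scale (SE 0.17, adjusted p = 1.23e-07). Its endothelial log2 fold change was 0.12 (SE 0.14). In mesangial cells it was 0.63 (SE 0.17) and did not pass the adjusted threshold. The number of genes with a difference was 45 without KO mouse 1, 71 without KO mouse 2, 46 without WT mouse 2 and 65 without WT mouse 3.

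**Figure D3:**
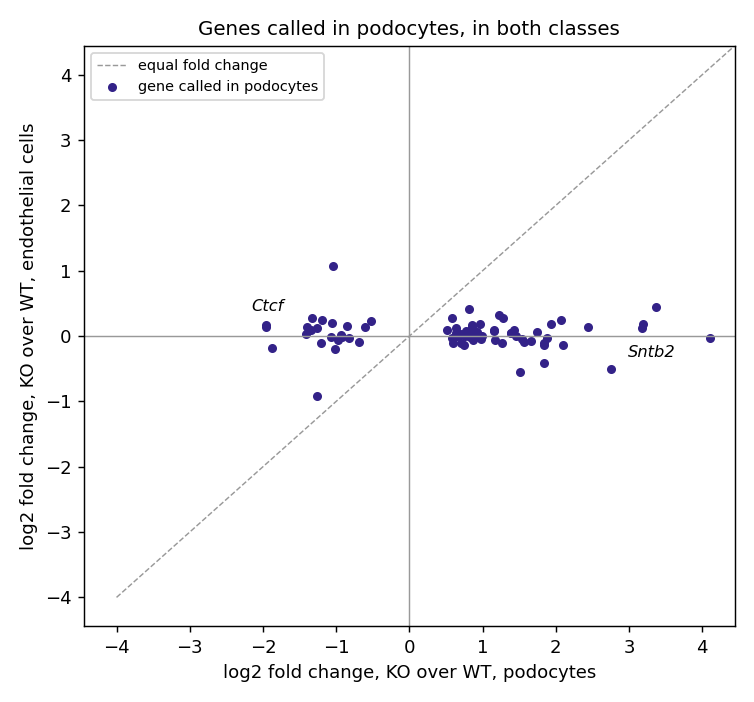
Log2 fold change of KO over WT in podocytes (horizontal axis) and endothelial cells (vertical axis) for the 79 genes called in podocytes and tested in both, each a point; the dashed line marks equal values. Endothelial values lie between -0.91 and 1.07.

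The 5 other classes had no gene past the threshold in edgeR. Arterial endothelial cells had 206 genes at an unadjusted p under 0.05 of 8387 tested, cells of the loop, distal tubule and collecting duct 344 of 8151, lymphocytes 30 of 2169, macrophages and dendritic cells 105 of 5199, and proximal tubule cells 153 of 8982. Each of these counts lay below the 5% of tested genes that chance gives. DESeq2 called 1 gene in cells of the loop, distal tubule and collecting duct and 0 in the other 4. Cyp26b1, a retinoic acid hydroxylase chosen after its values were seen, was the 1 call in cells of the loop, distal tubule and collecting duct without KO mouse 4 and the 1 call in macrophages and dendritic cells without KO mouse 2.

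Among 58 ligand and receptor pairs between the 3 filter cell types, both genes were measured in 37. In none did the ligand in the sending class or the receptor in the receiving class pass the edgeR threshold, and none passed with DESeq2. In 1 of the 37, Bmp4 and Bmpr2, either gene had an unadjusted p under 0.05.

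The share of podocytes was 20.1% ± 7.50 of kept cells in KO and 24.3% ± 13.2 in WT mice (SD, n = 4 each; exact permutation p = 0.686). Endothelial cells made up 41.5% ± 5.88 and 44.4% ± 10.6 (exact permutation p = 0.629), and mesangial cells 4.31% ± 1.32 and 3.93% ± 0.37 (exact permutation p = 0.714). None of the 11 classes passed (exact permutation tests, p from 0.286 to 0.886, adjusted p from 0.786 to 0.886). With 70 assignments, a single class with fully separated genotypes could not have passed after adjustment over the 11 classes. Without WT mouse 2 the podocyte difference was 2.24 percentage points instead of -4.19. Glomeruli were sieved and cells filtered on UMIs, which can set these shares. The median number of UMIs per podocyte was 4419 ± 1426 in KO and 5033 ± 1493 in WT mice (exact permutation p = 0.6).

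**Figure D4:**
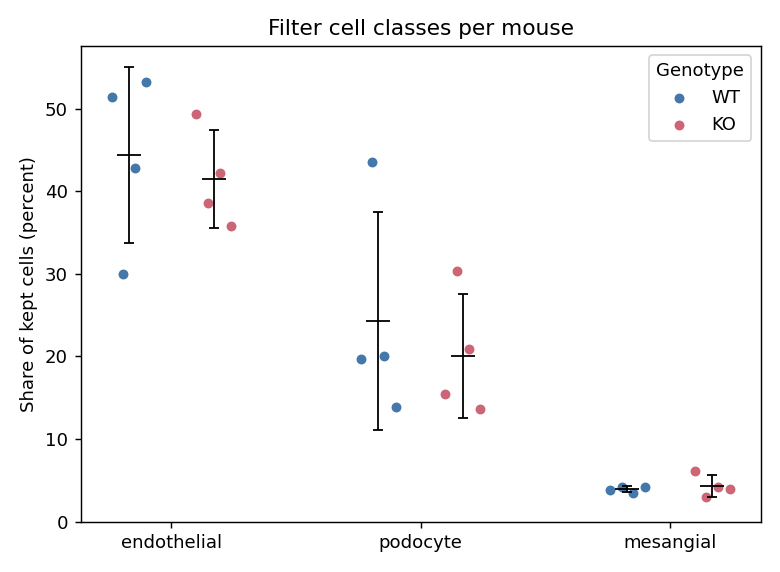
Share of kept cells in percent (vertical axis) for the 3 filter cell types; points are mice, bars the mean ± SD of 4 mice per genotype. The WT podocyte shares run from 13.8% to 43.6% and the KO shares from 13.6% to 30.3%.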

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

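The splits of the mice for the podocyte, endothelial and mesangial gene counts and the tests of depth, strain and passenger differences were chosen after those results were seen.

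The KO effect differed between podocytes and endothelial cells by the interaction test for 111 genes. Only the real grouping, 1 of the 35 splits of the 8 mice into 4 and 4, gave as many, and the highest other split gave 43, so chance can be excluded for this count if the 8 mice are exchangeable. For the 97 podocyte genes it was again 1 of 35, with 31 in the highest other split. Same-numbered mice correlated above 0.1 in podocytes, and only 8 of the splits part all same-numbered mice, too few for a share under 0.05. Within these 8 splits the real counts were 97 and 111 and the highest others 0 and 0. This tally was added after the counts were seen. In endothelial and mesangial cells the real count was 0, which all 35 splits reach by construction, so the splits decide nothing there. The highest other splits gave 130 and 84 genes, both setting mice 1 and 4 of each genotype against mice 2 and 3, which points to a structure of the samples. This split sets the 3 males and the female WT mouse 4 against 4 females, so sex stays open as its source. It also follows the mouse number exactly, so a batch that goes with the number stays open too. The real count was also 0 in the 5 other classes, where the splits again decide nothing and the highest others were 27 in arterial endothelial cells, 12 in cells of the loop, distal tubule and collecting duct, 37 in lymphocytes, 4 in macrophages and dendritic cells and 115 in proximal tubule cells.

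Genes were called in podocytes and none in endothelial or mesangial cells. Podocyte sums thinned to the mesangial totals called 20 genes instead of 97. This argued against lower depth of the mesangial sums only for changes as strong as those still called. Smaller mesangial changes stay open, since most podocyte calls were lost at that depth too. Lower endothelial depth was argued against by endothelial UMI totals above the podocyte totals in 6 of 8 mice. A strain or passenger difference present in every cell type would move the same genes in endothelial cells, where their median log2 fold change, signed by the podocyte direction, was 0.012 over 78 genes (-0.04 over 51 genes in mesangial cells). Sntb2, 1299 kb from Ctcf, was at 0.12 (SE 0.14) in endothelial cells but at 0.63 (SE 0.17, edgeR adjusted p = 1.00) in mesangial cells, against 3.18 in podocytes, so a smaller rise of Sntb2 in mesangial cells stays open. A hypothesis is that loss of Ctcf in podocytes may drive these changes.

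Of 134 groups of 4 values examined, 9 held a mouse far from the rest, where chance gives about 1 in 20. In KO mouse 4, mt-Nd1 in podocytes was at 8389 CPM, Kap at 1879 CPM in podocytes and 2742 CPM in endothelial cells, and mt-Cytb in endothelial cells at 12729 CPM. In KO mouse 1, Ifit2 in podocytes was at 2.03 CPM against 4.66 to 4.93. In WT podocytes, Mustn1 was at 23.2 CPM in mouse 4 (others 12.0 to 13.8), Rarres1 at 341 CPM in mouse 4 (others 296 to 300.4), Calca at 21.3 CPM in mouse 3 (others 29.4 to 29.6) and Rhpn1 at 807 CPM in mouse 2 (others 499 to 517).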

How the results depend on the processing

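Podocyte clusters alone, mice 4 left out together, the mixed cluster added and thinning to mesangial totals were alternatives chosen after seeing the data. Ctcf in podocytes kept its direction and call in all 29 alternatives, and the endothelial count stayed at 0 in all 25. The 97 podocyte genes became 178 with DESeq2, 62 with library A only, 17 with equal cells and UMIs, 17 and 27 in podocyte clusters 5 and 8 alone, and 20 at the mesangial totals; leaving out a mouse gave 29 (WT mouse 1) to 98. Fewer cells, UMIs or mice entered these alternatives, apart from DESeq2. The interaction count was 45 to 115 with a mouse left out. The mesangial count was 5 with no filter on low counts. The cause of the other differences was not tested.

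The mouse number was not taken as a pairing in the main test. Same-numbered mice correlated at 0.136 to 0.469 in podocytes, above 0.1 for every pair. KO mice 1, 2 and 3 correlated best with the WT mouse of their own number in all 3 classes. Their values were 0.583, 0.469 and 0.409 in endothelial cells and 0.366, 0.293 and 0.172 in mesangial cells. KO mouse 4 did so only in mesangial cells (0.038), and had 0.016 in endothelial cells. A batch shared by same-numbered mice therefore stays open. With the number as a replicate block, podocytes had 104 genes and the interaction 104. Arterial endothelial cells had 1 (Mgp), and cells of the loop, distal tubule and collecting duct 2 (Pappa, Cyp26b1). The block moved no other count past the adjusted threshold by more than 1.5 times. Genes at an unadjusted p under 0.05 in edgeR did move, from 172 to 375 in endothelial and from 188 to 376 in mesangial cells. With a mouse left out, cells of the loop, distal tubule and collecting duct had 0 to 1 calls, as had macrophages and dendritic cells.

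Lists past the threshold became 0 with an estimated correlation in all 3 classes, 3 in podocytes and 3 in mesangial cells with sex as a covariate, 3 and 2 with free RNA subtracted, and 3 in mesangial cells without both mice numbered 4. With a mouse left out they ran from 3 to 8 in podocytes, 0 to 8 in endothelial cells and 3 to 8 in mesangial cells. With free RNA subtracted, mt-Nd1 in podocytes reversed to -0.23 and mt-Cytb in endothelial cells to -0.85; Serpinb6b reversed to -0.017 in podocyte cluster 5. The endothelial share difference was 1.65 points over filter cells only. With a mouse left out the share difference ran from -7.68 to 2.24 points for podocytes, -7.68 to 0.082 for endothelial and -0.223 to 0.828 for mesangial cells. Of 16 genes named by the rule and called in podocytes besides Ctcf, 5 kept their call in all alternatives. The 3 named outside the rule after their values were seen kept it wherever they were tested. Gnai1 and Mnd1 were tested in 29 alternatives and Itgae in only 25. Over these 19 genes, 85 of 547 values lost the call and none reversed. Free RNA subtraction cannot change class shares and was not run for them. Thinned 2-fold changes were recovered in 49% of genes in mesangial cells, whose smallest sum held 321383 UMIs.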

Other observations

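The tests of single mice behind the unfolded protein response values and of gene density, and the neighbours named here, were chosen after results had been seen.

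Along the genome, of 96 genes called in podocytes other than Ctcf, 16 had another called gene within 500 kb, against a median of 8 and a 95th percentile of 16 in 10000 random sets matched on expression (permutation p = 0.0527, adjusted 0.0527), which leaves open whether called genes lie near one another. Of the 71 genes that rose, 10 started within 100 kb of a gene enriched in WT podocytes, against a median of 3 and a 95th percentile of 6 (permutation p = 0.0018, adjusted 0.0036 over both tests). Gene density was argued against, since sets matched also on the number of neighbouring genes gave a 95th percentile of 7 (permutation p = 0.0035). Examples are Lxn near Rarres1, Npdc1 near Clic3 and Serpinb9 near Serpinb6b, whose neighbours had log2 fold changes of 0.42, -0.28 and 0.12, none past the threshold. Over all 13 such pairs the neighbour had a negative log2 fold change in 9 and a positive one in 4. The pairs are not independent, since Nupr1 and Npdc1 each recur. Of 16 podocyte markers 0 had a positive log2 fold change, so the count shows nothing particular to neighbours. As a hypothesis, some genes may have come under the influence of nearby podocyte-active regions once Ctcf was lost; no chromatin data were analysed here.

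Genes of the integrated stress and unfolded protein response list had a mean log2 difference of -0.09 in endothelial and -0.21 in mesangial cells of KO mice. The exact permutation p of the list mean was 0.257 and 0.0857, so chance was not excluded for either; KO was below WT in all 4 mouse numbers in both classes, but 4 pairs cannot give an exact 2-sided sign-flip p under 0.125. In mesangial cells the smallest share of the difference left without any one mouse was 0.719, without WT mouse 3. This argued against a single mouse setting the list mean. Leaving out single mice ended the camera call for 0 of 8 mice. That call used the preset correlation, at which 19 of 35 splits gave as many list calls, so its persistence decides nothing here. In endothelial cells the difference kept 0.565 of its size without WT mouse 2, above the bound of 0.5 set after the result was seen, but whether the camera call rests on single mice stays open, since it was lost without any of 4 mice (camera adjusted p = 0.0923 without KO mouse 1, 0.0657 without KO mouse 4, 0.267 without WT mouse 2 and 0.0671 without WT mouse 3) and with sex as a covariate (0.0704). The number of lists past the threshold was reached in 30 of 35 splits in podocytes (real 5, highest other 12), 32 in endothelial cells (real 4, highest other 10) and 19 in mesangial cells (real 5, highest other 8), so chance cannot be excluded for these counts.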
